A study of Mus musculus with 6 samples.

How the data were processed

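RNA was sequenced from SLAM-LSK cells, the sorted fraction of mouse bone marrow that is enriched for haematopoietic stem cells. The fraction lacks lineage markers and CD48 and carries Sca-1, c-Kit and the SLAM receptor CD150. The labels assign 3 libraries to wild-type (WT) C57BL/6 mice and 3 to mice heterozygous for the Mecom R751W allele, the group named MecomWT:R751W. The labels call the libraries biological replicates and do not state that each came from a separate mouse, so p-values measure the spread between these samples. Per the labels' protocols, cells were sorted into a lysis reagent, and several library kits are listed by input amount, including one with ribosomal RNA depletion for low input. Which kit made these libraries is not given in the sources used here.

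The authors deposited 1 table of TPM (a read number divided by gene length and scaled to the same total in each library) for 18465 genes, with 1 column per library that sums to 1000000. Per the submitters' processing notes, the genome build mm10 and the tool DESeq2 were used, with no role stated for the tool. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here. All 18465 symbols matched a RefSeq table of the assembly GRCm38.p6, the same assembly as mm10, which gave gene types and coordinates. Of the rows, 12552 were protein-coding genes and 5913 were other genes.

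TPM keeps no depth of its own. Within each gene, however, the 6 values stood in ratios of whole numbers once 1 factor per library was divided out, and whole reads were implied for 100.0% of genes within a tolerance of 0.001 reads. On simulated tables the same procedure recovered 98.29% of genes exactly. The implied gene length was a whole number of bases within 0.05 bp for 99.17% of genes. Among 403 tRNA, snoRNA and snRNA genes, 91.8% of implied lengths lay within 1 bp of the RefSeq length. The implied totals were 11300080, 10886540 and 12378149 reads in WT replicates 1, 2 and 3, and 10657540, 10427533 and 12270900 in MecomWT:R751W replicates 1, 2 and 3. The median gene had 1013 implied reads over the 6 libraries together and the smallest had 18, so genes with few reads are missing from the table. These implied reads describe the depth and enter 1 added alternative.

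The test was limma (version 3.58.1 in R 4.3.3) on log2(TPM + 1), with a mean-variance trend and genotype as the only term, over genes with a mean of at least 1 TPM across all 6 libraries. Two-sided p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A log2 fold change is on the log2(TPM + 1) scale, which understates the change of low genes, and is given with its standard error (SE). Gene lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists tested. Camera with an estimated correlation and fry were run beside it. Mecom was also tested by an exact two-sided permutation test, for which 3 libraries against 3 allow a smallest p of 0.1. Tables of implied reads and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

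The design, the alternatives, 28 gene lists and the rule for named genes were fixed before the data were examined. The rule named Mecom and 18 haematopoietic transcription factors whatever their values. It also named, per direction, the 12 genes of largest change past the adjusted threshold whose groups did not overlap. Where fewer passed, the places were filled by the smallest unadjusted p among such genes with an absolute log2 fold change of at least 1. Predicted genes, pseudogenes and antigen receptor segments were left out of this part. Up to 4 members of smallest unadjusted p were named per list. Where the log2 fold change of a named gene exceeded its SE and leaving out 1 library moved it by over 1.5 times, the value without that library is given beside it. Leaving out a library also moved the median log2 fold change of all genes. It was -0.065 without WT replicate 2 and 0.053 without MecomWT:R751W replicate 2, and values are given without a correction for this. Counts and list tests are over all genes, and the values of some genes that the rule names are not reported here. Of the lists, 26 were tested. The B cell and plasma cell list had 2 tested members, and the pattern for mitochondrially encoded proteins matched 0 symbols, so a list of 13 such genes under their RefSeq names was added after the data were seen.

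Other settings fixed beforehand changed the pseudocount to 0.1 or 5, the smallest mean TPM to 5 or none, the scaling between libraries, the variance estimate, the weighting of libraries, the replicate block and the set test, and left out each library in turn, with the filter on low values applied again over the remaining libraries, so that members near it can enter or leave a list. Rows of small and ribosomal RNA, 152 genes with 38.71% to 44.06% of TPM, were left out in another. Added after the data were seen were fits over protein-coding rows alone, with TPM as deposited or rescaled to a total of 1000000, a fit over all rows divided by the protein-coding total, and limma-voom on the implied reads.

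The test was checked on simulated tables with the depth of these libraries, in which 16618 genes passed the filter. Each gene was given the spread typical of its mean level. Differences in spread between genes of like level were not simulated, so the shares below may be too favourable. Of 98 genes changed by 1 on the log2 scale, 63.3% were called in the right direction, and of 95 changed by 2, 88.4% were, with 8 unchanged genes called. Over 11391 protein-coding rows of the same simulation, the shares were 82.4% and 97.0%, with 7 unchanged genes called. With voom they were 82.7% and 93.7%, with 12 unchanged genes called. A shifted list was recovered by camera, and 0 of 24 unshifted lists were called. The simulated genes were drawn independently, so this check does not bear on false calls of lists whose members are correlated. In the real libraries the estimated correlation was 0.743 for immediate early genes.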

Results

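The transcriptome of SLAM-LSK cells, a bone marrow fraction enriched for haematopoietic stem cells, was compared between 3 WT samples and 3 samples heterozygous for the R751W allele of Mecom. Mecom encodes a zinc finger transcription factor, also known as EVI1 in its shorter form, that is needed to maintain stem cells. The title of the series sets MECOM against GATA2 in leukaemia and in mast cell differentiation, and the comparison asks how 1 altered allele changes expression in normal stem cells. Protein-coding genes took 25.87% to 30.11% of TPM and short non-coding RNAs 49.85% to 53.24%. Mean pairwise correlations of log2(TPM + 1) across genes were 0.982 within WT, 0.981 within MecomWT:R751W and 0.979 between them, where genes are not independent replicates. The nuclear RNA Xist was at 228.3 to 294.1 TPM in all 6 libraries, and 0 of 4 Y-linked genes searched were listed.

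Mecom itself was read at 38.2 ± 4.17 TPM in WT and 45.0 ± 5.53 TPM in MecomWT:R751W cells (SD, n = 3 each). The gene lies on chromosome 3 from 29951296 to 30509759 in GRCm38. The log2 fold change of 0.23 (SE 0.14) did not pass limma's test (adjusted p = 0.958), and the exact two-sided permutation p was 0.2, against a smallest possible p of 0.1. The log2 fold change was 0.14 without MecomWT:R751W replicate 1. A gene total does not separate the altered transcript from the normal one.

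Gata2, the factor named beside MECOM in the title, was at 122 ± 9.64 TPM in WT and 121 ± 8.48 TPM in MecomWT:R751W cells, a log2 fold change of -0.01 (SE 0.12). None of the 18 haematopoietic transcription factors passed the adjusted threshold over all genes. Gfi1, a repressor that acts in stem cells and granulocyte precursors, passed when adjusted over the list alone (adjusted p = 0.015 by limma), at 3.01 ± 0.580 TPM in WT and 5.87 ± 0.476 TPM in MecomWT:R751W. Its paralog Gfi1b had a log2 fold change of -0.41 (SE 0.18), Zfpm1, the GATA cofactor FOG1, -0.25 (SE 0.12) and Spi1, which encodes PU.1, -0.28 (SE 0.17). The other members lay closer to 0. Runx1 stood at -0.03, Tal1 at -0.04, Lmo2 at -0.04, Lyl1 at -0.17, Fli1 at -0.09, Ldb1 at -0.07, Cbfa2t3 at -0.23 and Meis1 at -0.01 on the log2 scale. Erg stood at 0.07, Ikzf1 at 0.06, Gata1 at 0.19, Cebpa at 0.11 and Myb at 0.10. As a list they did not pass (median -0.04, adjusted p = 0.526, camera). Single libraries turned several of these signs. The median of all genes moved too, from -0.0037 to 0.053 without MecomWT:R751W replicate 2 and to -0.065 without WT replicate 2. Turns of about that size are not particular to these genes. Without MecomWT:R751W replicate 2, Gata2 stood at 0.05, Tal1 at 0.01, Lmo2 at 0.06, Runx1 at 0.07, Ldb1 at 0.07, Meis1 at 0.07 and the list mean at 0.08. Erg stood at -0.02 without WT replicate 2, Ikzf1 at -0.02 without MecomWT:R751W replicate 1 and Cebpa at -0.17 without WT replicate 3. Gata1 stood at 0.09 and Lyl1 at -0.11 without MecomWT:R751W replicate 1. Gata1 stood at 0.36, Zfpm1 at -0.16, Cbfa2t3 at -0.08 and Spi1 at -0.14 without MecomWT:R751W replicate 2. Lyl1 stood at -0.11 without WT replicate 3. Lyl1 stood at -0.29 and Spi1 at -0.44 without MecomWT:R751W replicate 3. Gfi1b stood at -0.27 and Spi1 at -0.17 without WT replicate 1.

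**Figure D1:**
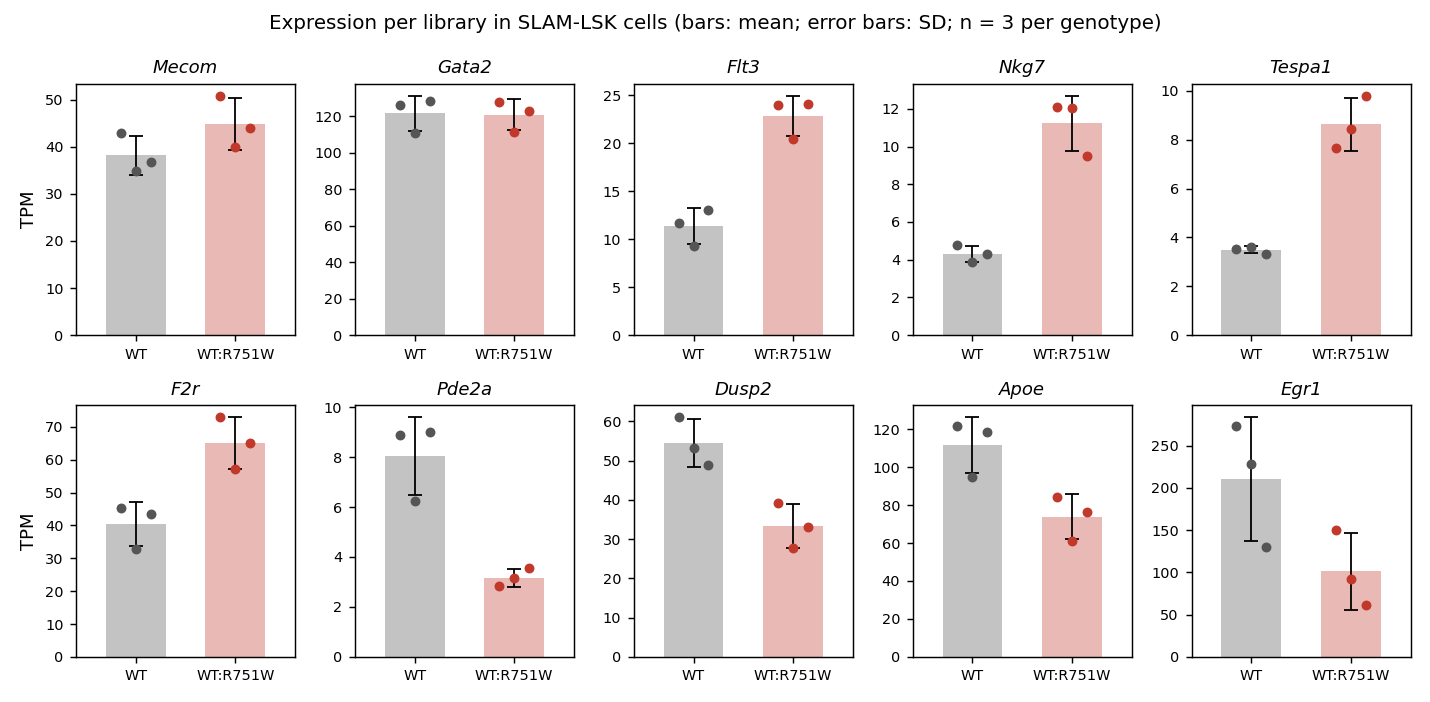
TPM of 10 genes in each library of WT and MecomWT:R751W SLAM-LSK cells, with bars at the mean, error bars for the SD and points for the 3 libraries per genotype. Mecom and Gata2 overlap between genotypes, while Flt3, Nkg7 and Tespa1 lie higher and Pde2a and Dusp2 lower in every MecomWT:R751W library.

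Among single genes, Nkg7 and Flt3 were among those that lay higher in every MecomWT:R751W library than in any WT library, and Pde2a was among those that lay lower. Nkg7, a granule protein of NK and cytotoxic T cells, was at 4.31 ± 0.432 TPM in WT and 11.2 ± 1.48 TPM in MecomWT:R751W (SD, n = 3). Flt3, the cytokine receptor of lymphoid-primed progenitors, was at 11.4 ± 1.90 and 22.9 ± 2.10 TPM. Pde2a, a cyclic nucleotide phosphodiesterase, was at 8.03 ± 1.56 and 3.17 ± 0.361 TPM. With limma over 16655 genes, 0 genes passed an adjusted p of 0.05 in either direction, and the smallest adjusted p was 0.0856. At an unadjusted p under 0.05 there were 457 higher and 538 lower genes, 995 in all, where chance alone gives 833. The 3 MecomWT:R751W values lay wholly above the WT values in 749 genes and wholly below in 782, which is 9.19% of genes, against 10% by chance. Without WT replicate 3, 6 higher and 2 lower genes passed, and without WT replicate 2, 1 higher and 1 lower. Without MecomWT:R751W replicate 1, 4 higher and 9 lower genes passed, among them Nkg7 and Car1 (adjusted p = 0.0375), Tespa1 (0.0339), and Ggt6, Fcer1g and Egr1 (0.0295).

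Fits added after the data were seen called more genes. Over protein-coding rows alone, 11394 genes tested, limma called 40 higher and 92 lower. These higher counts became 17, 25 and 63 without WT replicate 2, MecomWT:R751W replicate 1 and WT replicate 3, and the lower counts 40, 35 and 26 without WT replicate 1, WT replicate 2 and MecomWT:R751W replicate 2. With a pseudocount of 0.1 in that fit, the counts were 37 higher and 83 lower. With TPM rescaled to the same total over the protein-coding rows, limma called 8 higher and 9 lower of 12394 genes. Rescaling also brought more low genes past the filter and made the pseudocount smaller beside the values. With limma-voom on the implied reads it called 24 higher and 26 lower, and over all rows divided by the protein-coding total it called 0. A set of 14 genes was called by all 3 of the fits that made calls, of which 8 were still called over protein-coding rows with the replicate block and 12 without MecomWT:R751W replicate 2. Those higher in MecomWT:R751W were Flt3, Tespa1, Tjp1, Gm40514, Stxbp4 and F2r. Those lower included Pde2a, Fam174b, Trhr2, Adamtsl5, Dusp2, Gria3 and Apoe. Of these, Gm40514, Stxbp4, F2r, Fam174b, Gria3 and Apoe were named after their values were seen. F2r, the thrombin receptor PAR1, was at 40.5 ± 6.64 TPM in WT and 65.1 ± 7.83 TPM in MecomWT:R751W, and Apoe, a lipid carrier protein, at 112 ± 14.7 and 73.8 ± 11.8 TPM. For Flt3 the adjusted p was 0.142 over all rows, 9.63e-06 over protein-coding rows, 0.0191 after rescaling and 0.000126 with voom. For Pde2a the values were 0.149, 1.71e-05, 0.0256 and 0.00293. Nkg7 was called over protein-coding rows (adjusted p = 9.9e-07) and after rescaling (0.0191), but not with voom (0.0765).

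The rule for named genes gave 7 genes higher and 11 lower, none past the adjusted threshold over all rows. Beside Nkg7, the higher genes were Tespa1, a protein of T cell receptor signalling in thymocytes (log2 fold change 1.09, SE 0.17), Tjp1, the junction protein ZO-1 (1.05, SE 0.19), and Gimap4, a lymphocyte GTPase (1.42, SE 0.26). Ermap and Car1, both erythroid genes, and Matn4, an extracellular matrix protein, were near 1 TPM or under it in WT. Relative to their means, Matn4 and Car1 varied most of these 7 among the MecomWT:R751W libraries, with SDs of 3.30 and 3.92 TPM on means of 3.53 and 4.44. Beside Pde2a, the lower genes included Slc15a2, a peptide transporter (-1.20, SE 0.24), Fcer1g, the signalling chain shared by Fc receptors (-1.14, SE 0.30), and Tubb6, a beta tubulin (-1.04, SE 0.27). Adamtsl5 (-1.09), Pabpn1l (-1.11), Trhr2 (-1.17) and Ggt6 (-1.11) were at 6.39 TPM or less in both groups. The microRNA gene rows Mir721 (-1.0) and Mir3061 (-1.48) were also among them, and reads of any gene that overlaps them cannot be told apart from theirs here. Car1 stood at 0.80 and Mir3061 at -0.94 without MecomWT:R751W replicate 2.

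Of the 26 lists tested, 16 passed camera with the preset correlation, 7 higher and 9 lower in MecomWT:R751W. With an estimated correlation 0 passed, and the smallest adjusted p was 0.243. Without MecomWT:R751W replicate 2, 9 passed with the preset correlation. With fry, which asks whether the members of a list move one way, 1 passed. No member of any list passed the threshold over all genes, so counts of members below are of signs, or adjusted over the list alone.

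**Figure D2:**
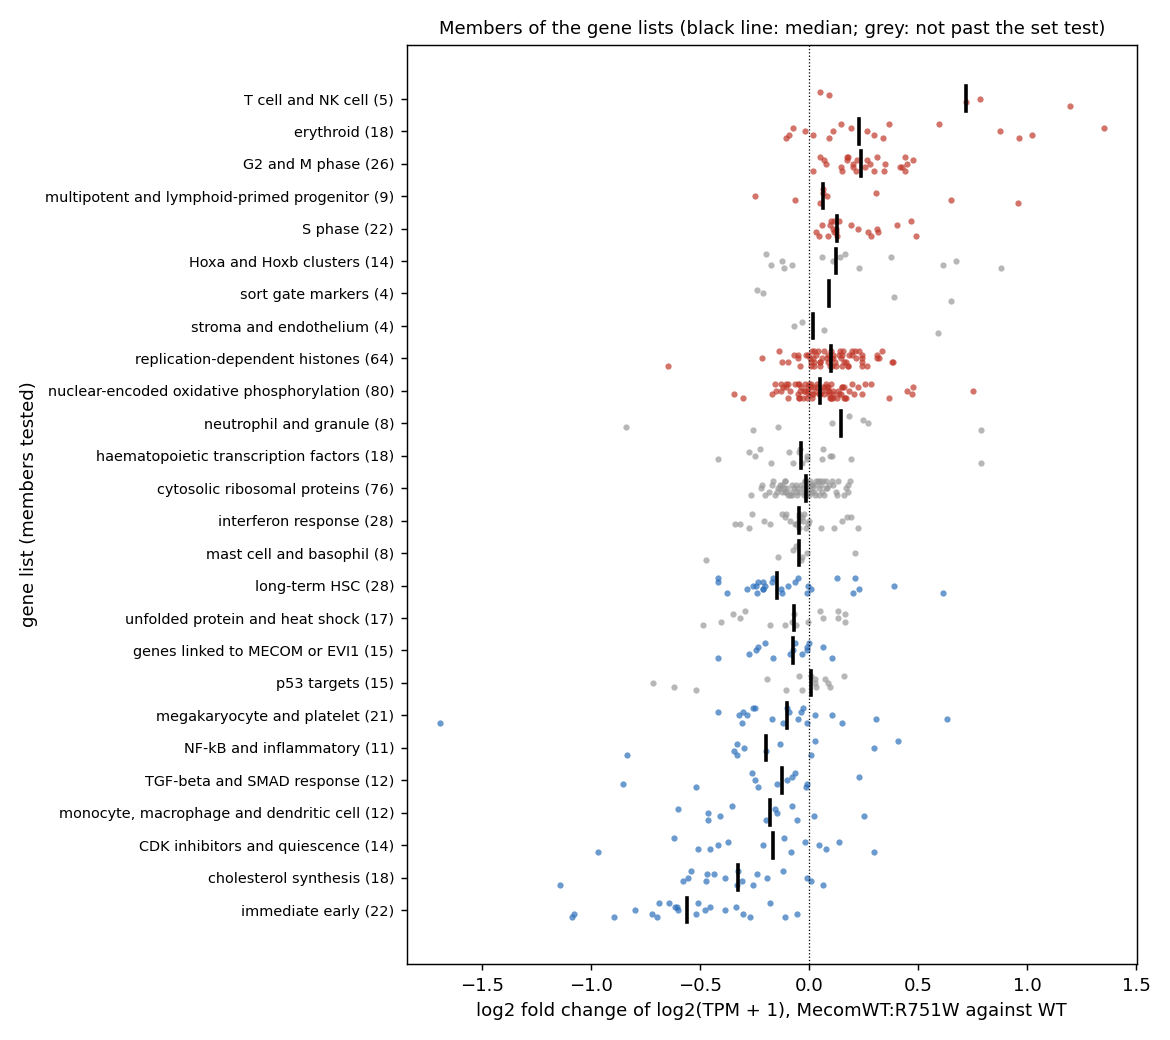
Log2 fold change of each tested member of the 26 gene lists, MecomWT:R751W against WT, with the black line at the median and lists ordered by mean. Red and blue mark the 16 lists past camera with the preset correlation, such as immediate early genes with all 22 members below 0 and G2 and M phase genes with all 26 above 0.

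Immediate early genes, the first to respond to stimulation of a cell, fell as a list in MecomWT:R751W cells. All 22 tested members had negative values, with a median of -0.56 (camera adjusted p = 9.63e-14, and adjusted p = 0.437 with an estimated correlation). Adjusted over the list alone, 5 passed, Dusp2, Egr1, Jun, Ier2 and Ier3. Dusp2, a phosphatase of MAP kinases, was at 54.4 ± 6.11 TPM in WT and 33.4 ± 5.66 TPM in MecomWT:R751W. Egr1, a zinc finger factor linked to stem cell quiescence, was at 211 ± 73.0 and 101 ± 45.4 TPM, and Jun at 282 ± 24.6 and 215 ± 14.1 TPM. The mean log2 level of the list was 5.82, 5.34 and 5.01 in WT replicates 1, 2 and 3, and 5.32, 4.71 and 4.51 in MecomWT:R751W replicates 1, 2 and 3, so the genotypes overlapped. Without WT replicate 1 the mean difference was -0.33 in place of -0.55.

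Genes of the cholesterol synthesis list also fell. Of 18 members, 16 were below 0, with a median of -0.33 (camera adjusted p = 1.21e-08, and adjusted p = 0.437 with an estimated correlation). Cyp51, the lanosterol demethylase, had a log2 fold change of -0.58 (SE 0.17) and Insig1, a sterol sensor partner, -0.55 (SE 0.20). Insig1 stood at -0.36 without WT replicate 1.

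Cell cycle genes rose by small amounts. All 26 genes of G2 and M phase were above 0, with a median of 0.24 (camera adjusted p = 6.51e-12, and adjusted p = 0.437 with an estimated correlation). All 22 genes of S phase were above 0 too, with a median of 0.13 (adjusted p = 2.24e-06, and adjusted p = 0.486 with an estimated correlation), and their mean of 0.19 became 0.11 without WT replicate 2. The median of all genes was -0.065 in that setting. No member of either list passed when adjusted over the list alone. Ube2c, a ubiquitin ligase partner of mitotic exit, was at 25 ± 1.45 TPM in WT and 34.4 ± 3.55 TPM in MecomWT:R751W, and Rrm2, a subunit of ribonucleotide reductase, at 15.7 ± 3.67 and 22.3 ± 1.69 TPM. Tpx2 (0.42), Hmmr (0.45), Bub1 (0.48), Cdt1 (0.31), Cdc6 (0.40) and Pola1 (0.31) had positive log2 fold changes. Replication-dependent histone genes rose as a list, with 53 of 64 above 0 and a median of 0.10 (adjusted p = 6.25e-05, and adjusted p = 0.675 with an estimated correlation). H4c18 stood at 0.38, H1f5 at 0.32, H1f1 at 0.31 and H2bc1 at -0.64. The mean of the list turned to -0.00 without WT replicate 1, where the list did not pass (adjusted p = 0.521). Copies of histone genes share sequence, and how shared reads were counted is not given. Bub1 stood at 0.32 and H4c18 at 0.25 without WT replicate 1. H1f5 stood at 0.21 without MecomWT:R751W replicate 1.

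Genes of cell cycle inhibition and quiescence fell, with 10 of 14 below 0 and a median of -0.16 (adjusted p = 0.0123, and adjusted p = 0.642 with an estimated correlation). Klf2 and Cdkn2d passed when adjusted over the list alone. Klf2, a factor of lymphocyte quiescence, was at 26.3 ± 11 TPM in WT and 12.8 ± 4.70 TPM in MecomWT:R751W, and Cdkn2d, an inhibitor of CDK4 and CDK6, at 14.9 ± 1.22 and 10.3 ± 1.55 TPM. Cdkn1c stood at -0.42 and Btg1 at -0.37. The call was lost without MecomWT:R751W replicate 2 (adjusted p = 0.134). Cdkn1c stood at -0.25 without WT replicate 3. Btg1 stood at -0.22 without WT replicate 1. Btg1 stood at -0.57 without MecomWT:R751W replicate 1. Btg1 stood at -0.20 without MecomWT:R751W replicate 2.

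**Figure D3:**
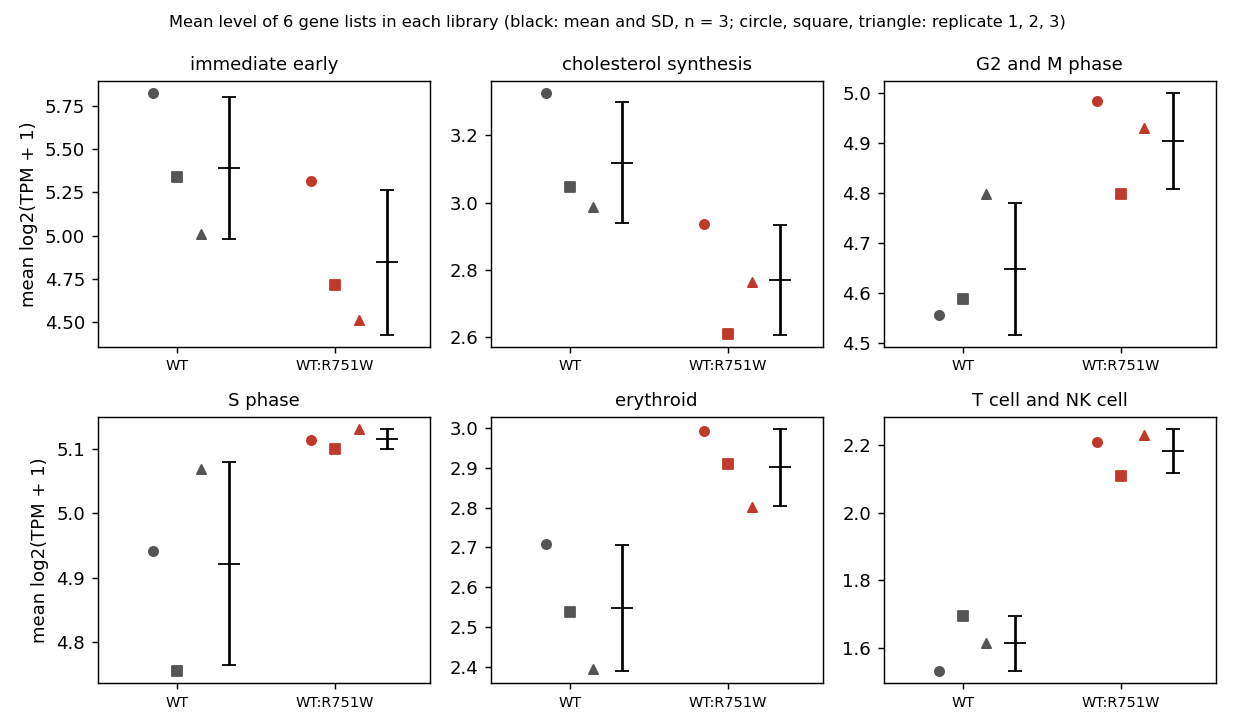
Mean log2(TPM + 1) over the members of 6 gene lists in each library, with the group mean and SD beside the 3 libraries of each genotype. Every MecomWT:R751W library lies below every WT library for cholesterol synthesis and above them for S phase, erythroid and T cell and NK cell genes, while immediate early genes overlap from 4.51 to 5.32 and from 5.01 to 5.82.

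Lists of other blood lineages moved in different directions. Erythroid genes rose, with 14 of 18 above 0 and a median of 0.23 (adjusted p = 1.83e-05, and adjusted p = 0.437 with an estimated correlation). Rhd, Ermap, Klf1, Car1 and Sptb passed when adjusted over the list alone. Klf1, the erythroid master factor, was at 1.81 ± 0.690 TPM in WT and 4.16 ± 1.23 TPM in MecomWT:R751W, and Rhd, a blood group antigen, at 0.690 ± 0.0943 and 2.34 ± 0.676 TPM. These levels are low, and over genes with a mean of at least 5 TPM the call was lost (adjusted p = 0.517). T cell and NK cell genes rose, with all 5 tested members above 0 and a median of 0.72 (adjusted p = 1.83e-05, and adjusted p = 0.243 with an estimated correlation), and this was the list past fry (adjusted p = 0.0087). Of the 21 genes listed, 7 were in the deposited table. Nkg7, Thy1 and Cd4 passed when adjusted over the list alone. Thy1, which marks lymphoid cells, was at 1.65 ± 0.671 and 3.28 ± 0.521 TPM and Cd4 at 1.6 ± 0.643 and 3.53 ± 1.30 TPM, while Lck stood at a log2 fold change of 0.09. Of these, Nkg7 alone had a mean above 4 TPM in either group. Tcf7, a T cell factor under the filter, had the opposite direction (1.26 TPM in WT and 0.653 TPM in MecomWT:R751W), and with no filter on low values the mean of the list was 0.35 in place of 0.57 (adjusted p = 0.00455). Car1 stood at 0.80 without MecomWT:R751W replicate 2.

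Genes of multipotent and lymphoid-primed progenitors rose as a list of 9, with 7 above 0, a mean of 0.21 and a median of 0.07 (adjusted p = 0.0342, and adjusted p = 0.675 with an estimated correlation). Flt3 passed when adjusted over the list alone (adjusted p = 0.000384). Without MecomWT:R751W replicate 3 the list did not pass (adjusted p = 0.0825). Cd48, which the sort gate selects against, was at 1.68 ± 0.598 and 3.21 ± 0.915 TPM, and Lsp1 stood at -0.25. Genes of long-term stem cells fell as a list, with 21 of 28 below 0 and a median of -0.15 (adjusted p = 0.0422, and adjusted p = 0.675 with an estimated correlation). Cdkn1c stood at -0.42 (SE 0.18), while Hoxb5 stood at 0.62 (SE 0.20) and Slamf1, which encodes CD150, at 0.39 (SE 0.17). Genes linked to MECOM or EVI1 fell, with 12 of 15 below 0 and a median of -0.07 (adjusted p = 0.0422, and adjusted p = 0.675 with an estimated correlation), led by Gfi1b, Spi1, Tek (-0.24) and Mllt3 (-0.23). The means of these last lists turned to 0.00 and 0.01 without MecomWT:R751W replicate 2, and neither list passed there (adjusted p = 0.303 and 0.513). The median of all genes was 0.053 in that setting, so both means still lay below it. The stem cell list also lost its call without WT replicate 2 (adjusted p = 0.0564), WT replicate 3 (0.22) or MecomWT:R751W replicate 3 (0.0811), and the MECOM list without WT replicate 1 (0.304). Gfi1b stood at -0.27, Spi1 at -0.17 and Lsp1 at -0.16 without WT replicate 1. Spi1 stood at -0.14, Tek at -0.09 and Mllt3 at -0.11 without MecomWT:R751W replicate 2. Spi1 stood at -0.44 without MecomWT:R751W replicate 3. Cdkn1c stood at -0.25 without WT replicate 3. Mllt3 stood at -0.35 without MecomWT:R751W replicate 1.

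Megakaryocyte and platelet genes fell, with 16 of 21 below 0 and a median of -0.10 (adjusted p = 0.0422, and adjusted p = 0.675 with an estimated correlation). Thbs1, an adhesive protein of platelets, was at 46.6, 15.5 and 3.29 TPM in WT replicates 1, 2 and 3 and at 3.67 ± 0.572 TPM in MecomWT:R751W, while Selp stood at 0.63. Thbs1 had a log2 fold change of -0.86 without WT replicate 1 and -2.59 without WT replicate 3, where it passed over all genes (adjusted p = 0.012). The list did not pass without WT replicate 1 (adjusted p = 0.169), WT replicate 2 (0.108), MecomWT:R751W replicate 2 (0.139) or MecomWT:R751W replicate 3 (0.238). Monocyte, macrophage and dendritic cell genes fell, with 10 of 12 below 0 and a median of -0.18 (adjusted p = 0.00922, and adjusted p = 0.437 with an estimated correlation). The class II genes H2-Ab1 (-0.46), H2-Aa (-0.46) and Cd74 (-0.41) led them with Klf4 (-0.60), which is also an immediate early gene. Without WT replicate 2 that list did not pass (adjusted p = 0.0943). Selp stood at 0.36 and Klf4 at -0.94 without WT replicate 3. H2-Ab1 stood at -0.30 without MecomWT:R751W replicate 2. Cd74 stood at -0.17 and Klf4 at -0.26 without WT replicate 1. H2-Aa stood at -0.25 without MecomWT:R751W replicate 1. Klf4 stood at -0.36 without MecomWT:R751W replicate 3.

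Mast cell and basophil genes, the lineage named in the title, did not pass. Of the 27 listed, 8 were tested and 7 were below 0, with a median of -0.05 (adjusted p = 0.34). Slc18a2, the vesicular monoamine transporter, was at 52.8 ± 8.48 TPM in WT and 38.4 ± 9.59 TPM in MecomWT:R751W, Cpa3, the mast cell carboxypeptidase, at 1.31 ± 0.705 and 1.66 ± 0.646 TPM, and Mitf and Srgn stood at -0.07 and -0.14. The mean of the list was 0.05 without MecomWT:R751W replicate 2, and Srgn was at 0.01 without WT replicate 1. Neutrophil and granule genes did not pass (median 0.15, adjusted p = 0.116), with Gfi1 past the threshold over the list alone, Padi4 at 0.27, Csf3r at 0.25 and Ngp at -0.84. That list passed without WT replicate 1 (adjusted p = 0.0393), and its mean was -0.09 without WT replicate 3. Stroma and endothelium genes did not pass (median 0.02, adjusted p = 0.138). Emcn, an endothelial sialomucin also found on stem cells, passed when adjusted over that list alone, at 13.7 ± 0.0710 and 21.3 ± 3.34 TPM, while Tie1, Col1a2 and Vcam1 stood at 0.07, -0.07 and -0.03, with Col1a2 at 0.17 and Vcam1 at 0.10 without MecomWT:R751W replicate 2 and Tie1 at -0.00 without MecomWT:R751W replicate 3. Of the B cell and plasma cell list, Sdc1 passed when adjusted over its 2 tested members alone, at a log2 fold change of -0.62. Sdc1 was at 1.85 ± 0.748 TPM in WT and 0.820 ± 0.262 TPM in MecomWT:R751W, and the genotypes overlapped. Cd79b stood at 0.07, or -0.06 without WT replicate 3, and the list had too few members for a set test. Genes of the sort gate, Kit (-0.21), Ly6a (-0.24), Slamf1 and Cd48, did not pass as a list (median 0.09, adjusted p = 0.453). Hoxa and Hoxb genes did not pass (median 0.12, adjusted p = 0.0634), though Hoxb8 passed when adjusted over the list alone, at 0.469 ± 0.393 and 1.65 ± 0.308 TPM, beside Hoxb6 (0.68) and Hoxb2 (0.37). The Hox list passed without WT replicate 3 (adjusted p = 0.00836). Slc18a2 stood at -0.25, Hoxb6 at 1.07, Hoxb2 at 0.65, Kit at -0.12 and Ly6a at -0.15 without MecomWT:R751W replicate 2. Ngp stood at -0.12, Hoxb6 at 0.37 and Hoxb2 at 0.22 without WT replicate 1. Ngp stood at -1.48, Padi4 at 0.12 and Hoxb6 at 1.13 without WT replicate 3. Csf3r stood at 0.15 without WT replicate 2. Csf3r stood at 0.15 and Hoxb2 at 0.15 without MecomWT:R751W replicate 3. Hoxb6 stood at 0.39 without MecomWT:R751W replicate 1.

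Among response pathways, NF-kB and inflammatory genes fell, with 7 of 11 below 0 and a median of -0.20 (adjusted p = 0.0408, and adjusted p = 0.642 with an estimated correlation). Tnfaip3, an inhibitor of NF-kB, stood at -0.84 (SE 0.28), Nfkb2 at -0.34, Nfkbia at -0.30 and Relb at -0.33. TGF-beta and SMAD response genes fell, with 11 of 12 below 0 and a median of -0.12 (adjusted p = 0.0408, and adjusted p = 0.675 with an estimated correlation), led by Skil (-0.85), Bambi (-0.52) and Ski (-0.25), with Tgfb1 at 0.23. Without WT replicate 1 neither list passed (adjusted p = 0.243 and 0.168), nor did either without MecomWT:R751W replicate 2 (0.064 and 0.139). The NF-kB list also lost its call without WT replicate 2 (0.11) or MecomWT:R751W replicate 3 (0.181). Nuclear-encoded genes of oxidative phosphorylation rose by little, with 51 of 80 above 0 and a median of 0.05 (adjusted p = 0.0288, and adjusted p = 0.675 with an estimated correlation), with Ndufa5 at 0.37, Ndufc1 at 0.47, Atp5g1 at 0.75 and Atp5g2 at 0.48. That list did not pass without WT replicate 2 (adjusted p = 0.101), WT replicate 3 (0.136), MecomWT:R751W replicate 1 (0.0976) or MecomWT:R751W replicate 2 (0.124). Tnfaip3 stood at -0.53, Relb at -0.20 and Skil at -0.43 without WT replicate 1. Nfkbia stood at -0.47 without MecomWT:R751W replicate 1. Skil stood at -0.56 without MecomWT:R751W replicate 3. Tgfb1 stood at 0.12 and Ndufc1 at 0.25 without WT replicate 2. Atp5g1 stood at 0.34 and Atp5g2 at 0.26 without WT replicate 3.

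The remaining lists did not pass. Genes of the unfolded protein and heat shock responses had a median of -0.07 (adjusted p = 0.0761), with Hspa5, the chaperone BiP, at 292 ± 50.2 TPM in WT and 207 ± 19.7 TPM in MecomWT:R751W, Atf4 at -0.40, Ddit3 at -0.35 and Dnajb1 at -0.31. The list passed without WT replicate 3 (adjusted p = 0.0141). For p53 targets the test and the mean pointed lower and the median was 0.01 (adjusted p = 0.34), with Bbc3 at -0.52, Cdkn1a at -0.62, Plk2 at -0.72 and Mdm2 at -0.19. The list passed without MecomWT:R751W replicate 1 (adjusted p = 0.0405). Interferon response genes had a median of -0.05, with 22 of 28 members below 0 (adjusted p = 0.534). The members named were Ifit2 at 0.22, Ifit3 at -0.34, Ifitm3 at 0.15 and Gbp3 at 0.19. That list passed without MecomWT:R751W replicate 3 (adjusted p = 3.67e-05), and its mean was 0.08 without MecomWT:R751W replicate 2. Cytosolic ribosomal protein genes had a median of -0.01 over 76 members (adjusted p = 0.521), with Rps21 at -0.26, Rps16 at -0.18, Rps10 at -0.22 and Rpl36 at -0.22. Its mean was 0.02 without WT replicate 1. The added list of 13 mitochondrially encoded proteins had a mean of -0.00 and a median of 0.02 (adjusted p = 0.997, camera). Ifit2 stood at 0.15, Ifitm3 at 0.06, Gbp3 at 0.02 and Mdm2 at -0.29 without WT replicate 2. Ifit2 stood at 0.12, Ifit3 at -0.57, Gbp3 at 0.09, Cdkn1a at -0.36 and Plk2 at -0.29 without MecomWT:R751W replicate 3. Ifit3 stood at -0.20, Cdkn1a at -0.21, Plk2 at -0.39, Mdm2 at -0.06, Atf4 at -0.27 and Ddit3 at -0.23 without WT replicate 1. Ifit3 stood at -0.53, Ifitm3 at 0.26 and Gbp3 at 0.32 without WT replicate 3. Ifit3 stood at -0.17, Plk2 at -1.29, Rps10 at -0.33 and Rpl36 at -0.34 without MecomWT:R751W replicate 1. Mdm2 stood at -0.08, Dnajb1 at -0.21, Rps10 at -0.09 and Rpl36 at -0.09 without MecomWT:R751W replicate 2.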

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

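The fits over protein-coding rows, the fit divided by the protein-coding total and the fit on implied reads were chosen after the data were seen, and the other alternatives before. Single genes other than Mecom changed side of the threshold in 94 of the gene values under an alternative, kept sign and side in 2829 and turned sign in 31. The main fit called 0 genes, so a change of side could only be from not called to called. Lists kept both in 479 values. With the sign kept, they lost their call in 66 and gained one in 9. They turned sign in 16, and some of these lost their call too, such as histones without WT replicate 1. The cause was not tested unless one is given.

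The counts of 0 higher and 0 lower genes became 1 and 1 with a mean TPM of at least 5, 4 and 1 with a robust variance estimate, and 0 and 1 with array weights. They became 40 and 92 over protein-coding rows, 8 and 9 with those rows rescaled to a total of 1000000, and 24 and 26 with voom on implied reads. Leaving out 1 library gave 0 to 6 higher and 0 to 9 lower. Of the lists, 16 passed, against 9 with array weights, 0 with an estimated correlation, 1 with fry and 9 to 16 without 1 library, where 9 came without MecomWT:R751W replicate 2. The log2 fold change of Mecom stayed above 0 and not called in every setting run, between 0.14 and 0.31. Over protein-coding rows the counts of 40 higher and 92 lower became 8 and 9 after rescaling, 51 lower without a mean trend, and 17 to 63 higher and 26 to 135 lower without 1 library. The lowest values came without WT replicate 2 (17 higher) and without MecomWT:R751W replicate 2 (26 lower).

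The labels do not give the replicate numbers as pairs, and the main fit did not pair the samples. The correlations of deviations between same-numbered libraries were 0.14, 0.0893 and 0.0833. Those between other numbers lay between -0.0862 and 0.00523, so each library correlated best with its own number. The protein-coding share of TPM also went with the number. It was 30.11%, 25.87% and 28.88% in WT replicates 1, 2 and 3. In MecomWT:R751W replicates 1, 2 and 3 it was 29.73%, 26.02% and 28.89%. These are hints of shared processing from the data and not from the design. With the replicate block, 0 higher and 0 lower genes and 13 lists passed over all rows, and 5 higher and 24 lower genes passed over protein-coding rows.

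Signs turned as follows. The median log2 fold change of all genes itself moved, to -0.065 without WT replicate 2 and to 0.053 without MecomWT:R751W replicate 2. Part of the ranges below is this common shift. With a mean TPM of at least 5 the mean of the Hoxa and Hoxb list was -0.075 and that of the sort gate list -0.019. Gata2 was at 0.0029 with quantile normalization. With array weights Lmo2 was at 0.028, Runx1 at 0.031, Col1a2 at 0.10 and the transcription factor list at 0.0295, and that list was at 0.0044 with voom. Without 1 library, log2 fold changes ranged from -0.077 to 0.046 for Gata2, -0.12 to 0.061 for Lmo2, -0.10 to 0.072 for Runx1, -0.13 to 0.032 for Tal1, -0.15 to 0.069 for Ldb1, -0.074 to 0.067 for Meis1, -0.018 to 0.14 for Erg, -0.024 to 0.16 for Ikzf1 and -0.17 to 0.36 for Cebpa. They ranged from -0.25 to 0.012 for Srgn, -0.22 to 0.11 for Vcam1, -0.20 to 0.17 for Col1a2, -0.00066 to 0.16 for Tie1, -0.0603 to 0.21 for Cd79b and -0.092 to 0.052 for Gimap5. List means ranged from -0.075 to 0.079 for transcription factors, -0.073 to 0.0198 for ribosomal proteins, -0.0027 to 0.18 for histones, -0.0903 to 0.21 for neutrophil genes, -0.25 to 0.076 for interferon response, -0.14 to 0.0046 for long-term HSC, -0.19 to 0.047 for mast cell genes and -0.18 to 0.0055 for genes linked to MECOM or EVI1. Depth limits low genes most: 31 genes were listed at 0 in at least 1 library.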

Other observations

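The genes of this paragraph lie outside the fixed rule, were chosen after their values were seen and stand for no tested group. Dntt, the terminal transferase of early lymphoid cells, was under the filter, at 0.251 ± 0.130 TPM in WT and 1.65 ± 0.671 TPM in MecomWT:R751W cells (SD, n = 3), on 3, 7 and 3 implied reads against 35, 16 and 31. With voom on the implied reads, Cxcr4, the niche-homing chemokine receptor, was higher (17.2 ± 2.28 and 30.0 ± 6.08 TPM, adjusted p = 0.0319), as were Socs2, a brake on cytokine signalling (adjusted p = 0.00398), and Cd55, a complement regulator (adjusted p = 0.00802). Chd7, a chromatin remodeller (adjusted p = 0.00451), Lhcgr, the luteinizing hormone receptor (adjusted p = 0.00937), and Ppp1r15a, a stress-induced phosphatase subunit (adjusted p = 0.0383), were lower. Over all rows their adjusted p by limma lay between 0.269 and 0.602, and Ppp1r15a passed there without MecomWT:R751W replicate 1 (adjusted p = 0.0295). The Gimap family, lymphocyte GTPases of similar sequence, moved by unlike amounts. Gimap4, which the fixed rule named, stood at a log2 fold change of 1.42. Values were 0.52 for Gimap8, 0.50 for Gimap9, 0.21 for Gimap6 and 0.04 for Gimap1. Gimap5 stood at -0.03 (SE 0.13), and its sign turned without WT replicate 3 and without MecomWT:R751W replicate 2. Gimap6 stood at 0.13 without MecomWT:R751W replicate 1 and 0.32 without MecomWT:R751W replicate 2.

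Of the tests below, the one on variance shared with non-coding rows was written before its result was seen, and the others were chosen after. The bounds for the third pattern replaced earlier ones, set without a basis, under which both of its explanations had been argued against, and so did the bound on single libraries in the second. Chance cannot be judged from the splits, since 3 libraries against 3 make 10 splits, too few for a share under 0.05. Over all rows the real split called 0 genes and the highest of the others 1, so 10 of the 10 splits called as many. The real split called 40 higher and 92 lower genes over protein-coding rows (56 in all for the highest other), 17 after rescaling those rows to the same total (highest other 0) and 50 with voom (highest other 4), and passed 16 lists (highest other 12). In each of these 4 cases 1 split, the real one, reached the count.

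The first pattern is that 0 genes were called over all rows, and 40 higher and 92 lower over protein-coding rows. Scaling by the non-coding share cannot be judged from these fits. Dividing by the protein-coding total with all rows kept gave 0 calls, but it also made the pseudocount smaller beside the values. The calls over protein-coding rows came with TPM as deposited, yet fell to 8 higher and 9 lower when those rows were rescaled to the same total. The number of rows in the adjustment is argued against, since the p-values of the all-row fit adjusted over protein-coding rows alone gave 0 calls. Taking the variance estimate from protein-coding rows and adjusting over as many rows as before gave 111 calls, so a candidate explanation is the shared variance estimate, whose prior degrees of freedom were 8.72 over all rows and 102 over protein-coding rows, with SEs that differed much for some genes (0.587 and 0.259 for Thbs1) and little for others (0.157 and 0.153 for Flt3). Non-coding rows are not needed for a low prior. It was 6.18 over the 12394 protein-coding rows tested after rescaling, and 5.66 over 11394 protein-coding rows with the replicate block. The counts of 40 and 92 may thus be too high.

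The second pattern is the lower level of immediate early genes. WT replicate 1 as the source cannot be told apart from genotype, since without it the mean difference was -0.33 in place of -0.55, nearer to 0 than the SD between libraries of 0.41 in WT and 0.42 in MecomWT:R751W. Handling that differed between libraries cannot be told apart either, since these genes respond to cell isolation, the library means overlapped and their exact two-sided permutation p was 0.2, in a design that cannot go below 0.1. The list kept its camera call with the preset correlation whichever library was left out. The differences between same-numbered libraries 1, 2 and 3 were -0.51, -0.63 and -0.50, although the labels do not give the numbers as pairs. Those of numbers 2 and 3 do not involve WT replicate 1. A difference that comes with the genotype remains open and untested.

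The third pattern is the higher level of Flt3, Nkg7, Tespa1 and Gimap4, the least changed of which had a log2 ratio of 1.01. Admixed T or NK cells, which the lineage gate would remove, cannot be told apart from a change within the sorted cells, since the 6 other listed genes had a median log2 ratio of 0.13 with an SD of 0.75, from -0.95 for Tcf7 to 1.14 for Cd4, and 0 of them reached a mean of 5 TPM. Of the 21 genes of that list, 7 were in the deposited table, and Cd3e, Cd3d, Cd3g, Gzma and Prf1 were not among them. Their absence gives no sign of such cells, but the rule by which genes were left out is not given. A larger share of multipotent progenitors may also raise Flt3, Nkg7, Tespa1 and Gimap4. It cannot be told apart either, since the 10 other listed genes had a median log2 ratio of 0.0822 with an SD of 0.88 and 7 above 0, and how far each should move is not known. The genotype as a source of a change within stem cells remains open.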
